A study of Mus musculus with 24 samples.

How the data were processed

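Endothelial cells were purified by flow cytometry from heart and lung of adult female C57BL/6J mice aged 8 to 10 weeks, 48 h after the start of tamoxifen treatment (2 mg by mouth on each of 2 days), per the labels' protocols. Tamoxifen activates CreERT2, here expressed from a Cdh5 transgene in endothelial cells, which deletes the floxed receptor genes. Deletion mice lacked VEGFR1 (gene Flt1, written R1), VEGFR2 (Kdr, R2), VEGFR3 (Flt4, R3), R1 with R2, R2 with R3, or all 3, and controls were littermates given tamoxifen, per the labels. Each library pooled sorted cells of 2 to 3 mice, per the labels. The 24 samples form 12 matrices, 6 of heart and 6 of lung, and each matrix holds 1 control and 1 deletion library. The matrices come from 8 experimental cohorts. Cohorts 69 (R1), 72 (R2), 70 (R1R2) and 120 (R2R3) gave both tissues, cohorts 83 (R3) and 82 (R1R2R3) gave heart, and cohorts 64 (R3) and 59 (R1R2R3) gave lung.

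Libraries were made with Chromium single-cell 3' reagents of version 2, per the labels' protocols. The submitters' processing notes list bcl2fastq 2.2.0, Cell Ranger 2.1.1, Seurat 4.0 and the mouse genome build mm10, without saying what each was used for. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, whole numbers that were not normalized, for 27998 genes. Whether the authors equalized depth between the libraries of a matrix is not given in the sources used here. A 3' tag measures the end of a transcript. The floxed exons are not given in the sources used here, so a receptor count need not measure the deleted part, and a gene whose tag lies outside that part checks nothing.

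The barcode suffixes (1 and 2) separate the libraries of a matrix, but no label, header or file ties a suffix to the control or to the deletion arm, nor says that a suffix means the same arm in every matrix. They are therefore called library 1 and library 2 throughout, and no receptor level was used to decide which was which. The planned fit of a deletion effect per receptor needed this map and was not made. The differences between libraries below have no known direction relative to the control. Cohort 120 was deposited with far fewer barcodes than the others: its lowest totals were 910 and 742 UMIs in heart and 1610 and 1470 in lung, while each of the other matrices listed 737280 barcodes per library.

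Barcodes with at least 1000 UMIs, at least 500 detected genes and at most 10% mitochondrial UMIs were kept as cells. Doublets were scored per library with scrublet (expected share 6%). It marked between 0 and 0.32% of the cells of a library and so removed almost none, and whether it missed doublets was not tested. Removal of the highest 6% of scores was added as an alternative. Cells were clustered per tissue with scanpy 1.11.5 and leidenalg 0.10.2. Counts were scaled to 10000 per cell and logged, 2000 variable genes were centred within each matrix, and 30 principal components, 15 neighbours, resolution 1 and seed 1 were used. Flt1, Kdr and Flt4 were left out of the clustering. Clusters were named from marker lists fixed before the data were examined. A name needed at least 3 markers at 2-fold or more over the remaining cells (1.5-fold for capillary markers) and 20 CPM (UMIs scaled to the library total), and leading genes, taken at 100 CPM or more, that did not go against it. These thresholds, and the limit of 0.8 on the median fold of the pan-endothelial markers below which a cluster could take the name of another cell type unless it carried at least 3 lymphatic or 6 venous markers, were set after the clusters' leading genes and library shares had been seen. Heart cells led by cardiomyocyte transcripts and cells led by platelet transcripts in either tissue stayed unnamed and outside the endothelial cells. Heart capillary clusters were named against the named vessel clusters.

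UMIs of endothelial cells were summed per library for comparisons within a matrix, and over both libraries of a matrix for heart against lung. Heart against lung used edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr, glmQLFit with robust estimation and glmQLFTest on 6 heart and 6 lung matrices. A gene was called at an adjusted p (Benjamini-Hochberg) of at most 0.05 and a difference of at least 2-fold. Camera in limma 3.58.1 tested 32 gene lists with its preset correlation, and again with the correlation estimated from the data. The 16 pathway lists were VEGF receptors, coreceptors and ligands, VEGF-responsive genes, angiopoietin-Tie genes, the Notch pathway, flow-responsive genes, junction genes, fatty acid uptake, hypoxia and glycolysis, p53 targets, apoptosis regulators, the G1/S and G2/M cell cycle, inflammatory activation, interferon response, MHC class I and II, and immediate early and heat shock genes. The marker lists covered aerocytes, lung general capillary, heart capillary, arterial, venous, lymphatic, endocardial, proliferating, pan-endothelial, immune, lung epithelial, fibroblast, pericyte and smooth muscle, cardiomyocyte, erythrocyte and platelet cells. DESeq2 1.42.0 was an alternative. Each cohort number marks a shared experiment per the labels. The deviations of a cohort's heart and lung matrices from their tissue means correlated at 0.604 in cohort 120, 0.331 in cohort 69, 0.271 in cohort 70 and 0.379 in cohort 72. The highest correlation of these heart matrices with any other lung matrix was −0.095, 0.091, 0.196 and 0.066. The cohort was therefore taken to pair the tissues, which the main fit in all 12 matrices leaves out. Matrices of a cohort also share their deleted receptors, so the source of the correlation cannot be told. With the cohort as a block, which uses the 8 matrices of the 4 shared cohorts, 2371 genes were called, against 2306 in the same matrices without it and 2327 in all 12.

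Between the libraries of a matrix there is 1 library per arm, so no test was made. Ratios of CPM (library 2 over library 1) had 5 CPM added to both. Conditional binomial 95% intervals were computed without that addition, and receptor log2 ratios given with an interval are also without it. Genes were counted when at least 2-fold apart, with an interval excluding 0 and at least 50 CPM in either library. For gene lists the median log2 ratio of members at 20 CPM or more was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these libraries only, since genes of a list vary together. Receptors were tested on the size of the log2 ratio (5 CPM added) without its sign, which needs no map of libraries to arms: cohorts whose label names the receptor against the others, with heart and lung averaged where a cohort has both (exact permutation, two-sided, 3 tests). The same test on list medians made 45 tests. A list with fewer than 3 members at 20 CPM in any matrix was left out, so these do not cover all 16 pathway lists. Shares of endothelial classes carry exact (Clopper-Pearson) 95% intervals. Intervals cover counting error only and leave out the spread between mice and between preparations.

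The genes named for heart against lung are the 12 with the largest fold in each direction among called genes at an average log2 CPM of at least 6 whose tissues did not overlap. For each matrix they are up to 4 counted genes on either side, leaving out mitochondrial, ribosomal protein, haemoglobin, Xist and predicted genes; 2 genes that this names in lung R1R2R3 are not reported here. Members of the fixed lists and the 3 receptors may be named anywhere. Positions come from the GENCODE vM21 annotation of GRCm38, the same assembly as mm10, counted from 1.

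In simulated counts drawn from the real means with known changes, the heart against lung test was scored on adjusted p and direction, without the 2-fold minimum. It recovered 42 of 50 genes changed 1.5-fold and all 50 at each of 2, 3 and 4-fold. By adjusted p alone, 6 unchanged genes passed among 11744 tested. The median size of the fitted log2 ratio was 0.59 at 1.5-fold and 1.00 at 2-fold. Recovery with the 2-fold minimum, which many of these genes would miss, was not scored. The count of genes 2-fold apart recovered 48 of 50 at 2.5-fold in simulated heart R1R2 libraries (3323 genes) and 50 of 50 in lung R2R3 (3231 genes), with 0 unchanged genes counted in either. These libraries were drawn from 1 profile with counting error alone. The 0 therefore does not cover false counts from spread between mice or preparations. Alternatives were other normalization, no filter on low counts, no fold minimum, the cohort block, each matrix or cohort left out, minimums of 500 and 2000 UMIs, doublets kept, all called cells, capillary cells alone, thinning to 1000 UMIs per cell, floors of 20 and 50 CPM, TMM between libraries, resolution 0.5 and naming by marker score. Added after the data had been seen were the removal of high doublet scores, the 8 matrices of shared cohorts without the block, fits without barcodes called in another library of the cohort, without lung cluster 19 or without cohort 120, and a clustering without genes 2-fold apart between libraries. Sizes of heart capillary clusters are not compared between libraries, because genes that lead them, Igfbp3 and Angptl4 among them, differed between libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.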

Results

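In heart, 30444 cells from 12 libraries passed the limits on UMIs, genes and mitochondrial share, and 28105 of them were endothelial. In lung, 24602 cells from 12 libraries passed and 20114 were endothelial. A heart library held 1419 to 3657 endothelial cells (89.9 to 93.9% of its cells), with 2263394 to 9916194 endothelial UMIs and a median of 1388 to 2466 UMIs per cell. A lung library held 1072 to 2871 endothelial cells (73.7 to 86.6%), with 2010521 to 11819992 endothelial UMIs and a median of 1528 to 3447. Total UMIs per library ran from 4912963 to 11304081 in heart and from 5562594 to 15998407 in lung. With both libraries of a matrix summed, expression correlated across genes at 0.973 or more between heart matrices and at 0.975 or more between lung matrices. Between the tissues it correlated at 0.839 or less. Genes are not independent replicates here.

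Flt1, which encodes VEGFR1, a receptor of high affinity for VEGF-A, was lower in library 2 in each of the 6 matrices whose label names R1. In heart, Flt1 in library 2 stood at 29.1% of library 1 in the R1 matrix (598 against 174 CPM), at 35.2% in R1R2 (672 against 236 CPM) and at 45.3% in R1R2R3 (645 against 292 CPM). The lung matrices were further apart, at 16.1% in R1 (500.5 against 80.4 CPM), 12.6% in R1R2 (458 against 57.7 CPM) and 12.7% in R1R2R3 (561 against 71.2 CPM). In the 6 matrices that do not name R1, library 2 stood at 87.9 to 119.7% of library 1. The log2 ratio, without added CPM, ran from −1.14 (95% counting interval −1.23 to −1.06, 3433 and 1624 counts) in heart R1R2R3 to −2.99 (−3.23 to −2.75, 921 and 170 counts) in lung R1R2. Flt1 lies on chromosome 5 at 147561604 to 147726011 of GRCm38, minus strand.

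Kdr, which encodes VEGFR2, the main signalling receptor for VEGF-A in endothelium, was lower in library 2 in each of the 8 matrices whose label names R2. In heart the level in library 2 was 45.3% of library 1 in R2 (476 against 216 CPM), 30.9% in R1R2 (518 against 160 CPM), 48.4% in R2R3 (438 against 212 CPM) and 28.8% in R1R2R3 (451 against 130 CPM). In lung it was 50.6% in R2 (389 against 197 CPM), 62.0% in R1R2 (384 against 238 CPM), 47.5% in R2R3 (420 against 199.5 CPM) and 70.4% in R1R2R3 (427 against 300.5 CPM). The log2 ratio without added CPM in lung R1R2R3, −0.51 with an interval of −0.62 to −0.40, was the smallest of the 8 in size. In the 4 matrices that do not name R2, the level was 87.6 to 122% of library 1. Kdr lies on chromosome 5 at 75932827 to 75978458, minus strand.

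Flt4, which encodes VEGFR3, the receptor of VEGF-C and VEGF-D, left 5 to 10 counts in library 2 of each of the 6 matrices that name R3, against 129 to 484 counts in library 1. This put library 2 at 2.30 to 6.84% of library 1, with a log2 ratio without added CPM of −4.23 (−5.31 to −3.31) in heart R3 and −5.44 (−6.51 to −4.55) in lung R2R3. With 5 CPM added to both libraries these were −2.38 and −2.95. In the 6 matrices that do not name R3, library 2 stood at 78.6 to 182% of library 1, the highest being heart R1 with 84 and 238 counts. Flt4 lies on chromosome 11 at 49609263 to 49652739, plus strand.

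Each receptor differed more between the libraries of cohorts whose label names it than between those of other cohorts, whichever library was lower. For Flt1 the unsigned log2 ratio, with 5 CPM added to both libraries, averaged 2.09 ± 0.73 (SD, 4 cohorts) where named and 0.17 ± 0.07 (4 cohorts) elsewhere, a difference of 1.93 (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.0286 over 3 receptors, 70 splits). For Kdr it averaged 1.10 ± 0.45 (5 cohorts) and 0.15 ± 0.04 (3 cohorts), a difference of 0.96 (exact permutation p = 0.0179, adjusted p = 0.0268, 56 splits). For Flt4 the averages were 2.61 ± 0.31 and 0.28 ± 0.19 on 5 and 3 cohorts, a difference of 2.33 with the same exact permutation p and adjusted p as Kdr. These are the smallest p-values that the splits can give. Several calls were lost when 1 cohort was left out: without cohort 64, 70, 72, 83 or 120 the exact permutation adjusted p was 0.0571 for each receptor, without cohort 82 it was 0.0571 for Kdr and 0.0429 for Flt1 and Flt4, without cohort 69 it was 0.0476 for each, and without cohort 59 it was 0.0286 for each. The differences themselves ran from 1.66 to 2.25 for Flt1, 0.79 to 1.11 for Kdr and 2.19 to 2.42 for Flt4 over these 8 omissions. In heart alone the differences were 1.31, 1.16 and 1.91 for Flt1, Kdr and Flt4, and in lung alone 2.62, 0.74 and 2.69, each with an exact permutation adjusted p of 0.1. The floxed exons are not known here, so these ratios do not measure how much functional receptor was left.

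**Figure D1:**
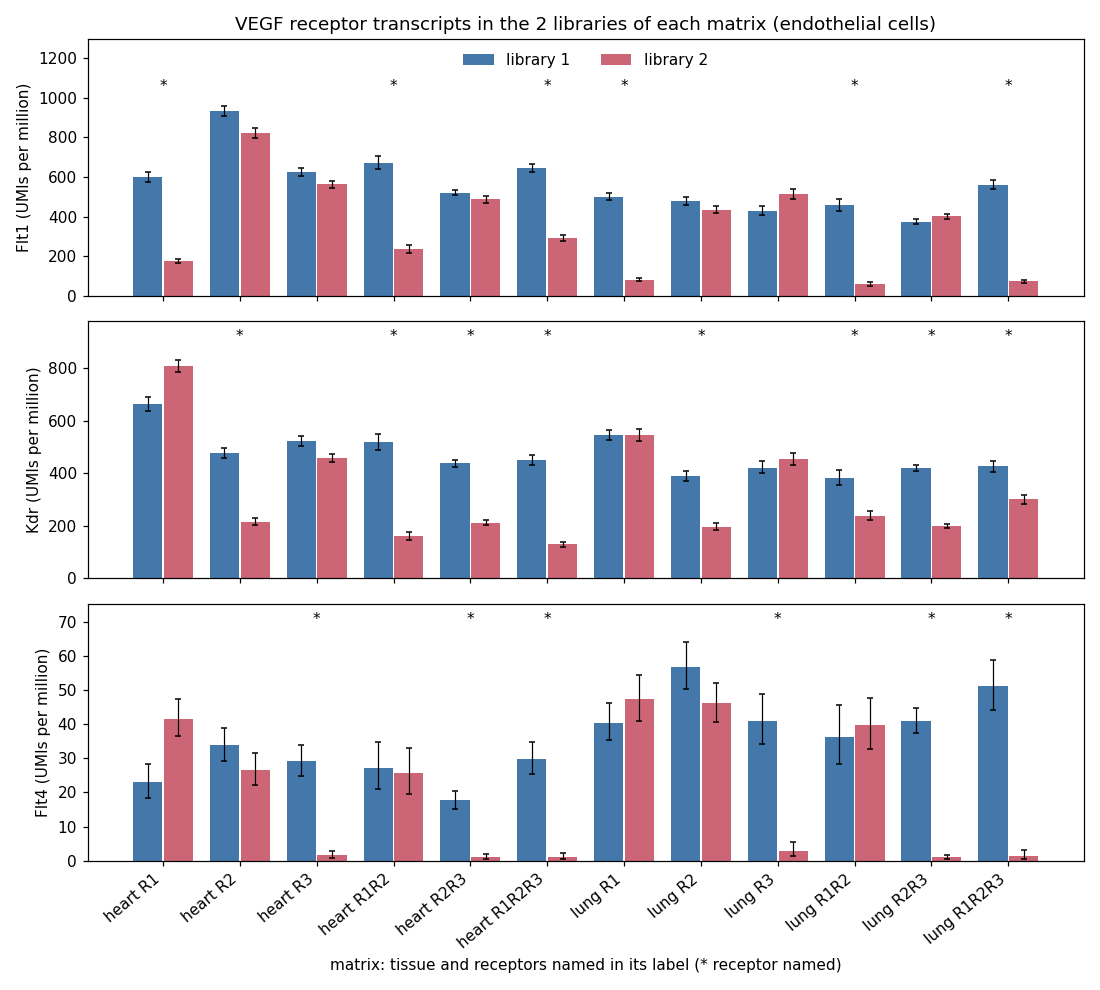
Flt1, Kdr and Flt4 in endothelial cells of each heart and lung matrix, as CPM (UMIs scaled to library size, vertical axis) in library 1 and library 2 with 95% counting intervals, an asterisk marking a receptor that the matrix label names. Flt4 in library 2 stands at 2.30 to 6.84% of library 1 where it is named and at 78.6 to 182% elsewhere.

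Lung endothelial cells expressed Hpgd, which encodes the enzyme that inactivates prostaglandins, at 2835 ± 161 CPM (SD, n = 6 matrices), against 1.21 ± 0.93 CPM in heart (n = 6). The mesenchymal and lung vascular transcription factor gene Foxf1 stood at 1363 ± 239 against 0.836 ± 0.483 CPM. Heart endothelial cells expressed the fatty acid carrier gene Fabp4 at 27760 ± 4212 CPM, against 318 ± 233 CPM in lung, and the nucleoside transporter gene Slc28a2 at 229 ± 19.7 against 1.30 ± 1.62 CPM. The log2 ratio of lung over heart was 11.05 for Hpgd (SE 0.32, adjusted p = 1.8e-13), 10.65 for Foxf1 (SE 0.26, adjusted p = 1.6e-14), −6.45 for Fabp4 (SE 0.48, adjusted p = 5.9e-08) and −7.50 for Slc28a2 (SE 0.45, adjusted p = 1.7e-08) by edgeR. In edgeR 2327 of 11837 genes were called, 1313 higher in lung and 1014 higher in heart. The count was 3827 without the filter on low counts (2249 and 1578) and 5924 without the 2-fold minimum (3157 and 2767). Both libraries of each matrix were summed, so each mean averages control and deletion cells, and the tissues were digested and sorted as separate suspensions.

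The largest lung over heart folds, taken from summed counts with 95% counting intervals, belonged to genes with few heart counts. The sodium channel gene Scn7a gave 3 heart counts, with 4 of 6 heart matrices at 0, and a fold of 5870 (2008 to 28467). The semaphorin gene Sema3c gave 11 heart counts and a fold of 3770 (2107 to 7553). Aard had a fold of 3212 on 4 heart counts, and Fendrr, a long noncoding RNA transcribed beside Foxf1, a fold of 2431 on 5. Hpgd reached 2243 (1811 to 2812, 84 heart counts) and Foxf1 1661 (1263 to 2232, 51 heart counts). Fibin reached 1580, Adgrl3 1373, the beta-1 adrenergic receptor gene Adrb1 623, Rasgef1a 480, Nckap5 465 and the carbonic anhydrase gene Car2 297, on 20, 6, 15, 34, 19 and 37 heart counts. In the 5 heart matrices that list them, barcodes of at most 100 UMIs held Hpgd at a mean of 149 CPM, Foxf1 at 54.7 and Scn7a at 20.6, against 1.21, 0.836 and 0.0524 CPM in heart endothelial cells. For Hpgd these barcodes held 163 to 299 CPM in libraries of heart R1, R2 and R1R2 and 5.5 to 9.4 CPM in heart R3 and R1R2R3. Hpgd in endothelial cells stood at 0 to 1.28 CPM in the former and 0.466 to 3.57 CPM in the latter. These low-UMI columns may partly hold swapped molecules of other libraries, but for Hpgd their level did not track that of endothelial cells. Whether the few heart counts are expression in heart cells was not tested. Toward heart the fold was 181 for Slc28a2 (144 to 230), 114 for the potassium channel gene Kcna5, 89.7 for the glycerol channel gene Aqp7, 86.0 for the transcription factor gene Meox2, which with Tcf15 drives fatty acid transport genes in heart endothelium, and 85.6 for Fabp4 (84.4 to 86.9). Timp4, Gm12002, Rbp7, Tcf15, Pparg, C1qtnf9 and Slc26a10 stood at 85.1, 83.8, 81.5, 75.0, 71.3, 66.2 and 57.8. The adjusted p of these 24 genes in edgeR ran from 8.7e-16 (Aard and Car2) to 3.2e-06 (Timp4).

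Much of the lung signal of the heart-higher genes came from a single lung cluster, number 19, of 345 cells with a heart capillary profile. Without it the log2 ratio of lung over heart moved to −11.53 for Slc28a2, −11.50 for Kcna5, −10.57 for Gm12002, −10.55 for Aqp7, −9.70 for Timp4, −9.53 for Rbp7, −9.15 for Fabp4, −8.34 for Meox2, −8.15 for C1qtnf9, −8.00 for Tcf15 and −7.73 for Pparg, while Slc26a10 went from −5.91 to −6.04. Leaving out the lung matrix of cohort 69 moved Slc28a2 to −8.57, Gm12002 to −7.48, Timp4 to −7.07 and Rbp7 to −6.98. Among lung-higher genes the fitted log2 ratio of Scn7a was 12.17 and went to 13.13 without the heart matrix of cohort 72, and that of Fibin went from 10.48 to 11.82 without the heart matrix of cohort 83. In all called cells, which include other cell types, it was 7.77 for Scn7a, 7.73 for Adgrl3, 8.76 for Fibin and 5.11 for Car2, and −5.37 for Meox2. A minimum of 500 or 2000 UMIs per cell put Hpgd at 12.47 or 12.33. Each gene kept its direction and passed in edgeR under these settings.

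Positions on GRCm38 are chromosome 8 at 56294585 to 56321043 for Hpgd (plus strand) and at 121084386 to 121088144 for Foxf1 (plus strand), chromosome 3 at 10204088 to 10208576 for Fabp4 (minus strand), and chromosome 2 at 66673425 to 66784914 for Scn7a (minus strand) and at 122426477 to 122461137 for Slc28a2 (plus strand).

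**Figure D2:**
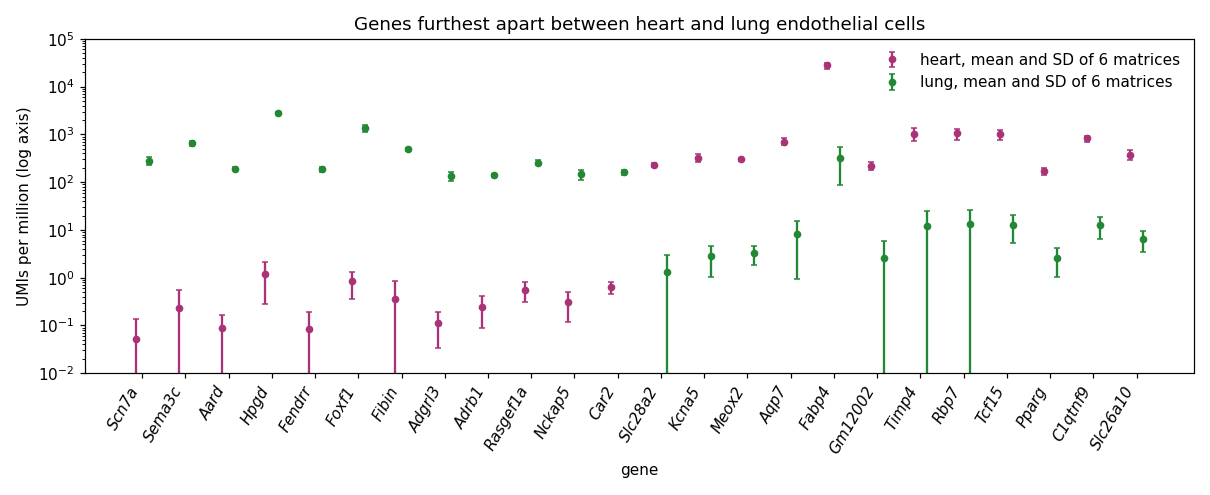
Mean CPM (UMIs scaled to library size, log axis) of 24 genes in heart and lung endothelial cells, with the SD of 6 matrices per tissue; bars that reach the bottom of the axis have an SD at or above the mean. Fabp4 stands at 27760 in heart against 318 in lung, and Hpgd at 2835 in lung against 1.21 in heart.

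Genes of fatty acid uptake were higher in heart in all 9 measured cases, with a median log2 ratio of lung over heart of −5.22. Besides Fabp4, the epidermal fatty acid carrier gene Fabp5 stood at 1164 ± 250 CPM in heart and 30.9 ± 11.2 in lung (log2 −5.22, edgeR adjusted p = 2.1e-10), the scavenger receptor gene Cd36 at 4346 ± 844 and 1977 ± 197 (−1.14, adjusted p = 1.5e-06), and the lipase anchor gene Gpihbp1 at 3307 ± 503 and 1555 ± 262 (−1.09, adjusted p = 3.0e-06; n = 6 each). Lpl, whose lipase frees fatty acids from lipoproteins, stood at 1217 ± 328 and 369 ± 70.1 CPM (−1.72), and its inhibitor gene Angptl4 at 80.4 ± 43.4 and 6.87 ± 4.17 (−3.55). The list was lower in lung by camera (adjusted p = 3.3e-10 over 32 lists; adjusted p = 0.0154 with an estimated correlation). With the cohort as a block the call with an estimated correlation was lost, as given with the marker lists below.

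Hypoxia and glycolysis genes were higher in heart in 6 of 11 cases and higher in lung in 0, with a median of −1.34. Ndrg1, a hypoxia-inducible gene, stood at 263 ± 35.9 CPM in heart and 49.4 ± 4.51 in lung (log2 −2.41, edgeR adjusted p = 5.4e-12), and the vasodilator gene Adm at 66.2 ± 18.3 and 10.8 ± 2.78 (−2.64, adjusted p = 5.3e-08). Camera gave the list an adjusted p of 1.5e-04, and an adjusted p = 0.0630 with an estimated correlation. Interferon response genes were higher in heart in 5 of 16 cases and higher in lung in 0, with a median of −0.69. Among them Ifit3 stood at 160 ± 38.3 CPM in heart and 71.4 ± 15 in lung (−1.16, edgeR adjusted p = 2.8e-05). The camera adjusted p of the interferon list was 8.7e-04, and adjusted p = 0.325 with an estimated correlation.

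Immediate early and heat shock genes, which respond to tissue handling as well as to signals in the animal, were higher in lung in 8 of 16 cases and higher in heart in 0. Fos stood at 207 ± 111 CPM in heart and 1049 ± 270 in lung (log2 2.35, edgeR adjusted p = 4.3e-05), and Egr1 at 97.3 ± 70.6 and 296 ± 72.4 (1.62, adjusted p = 0.0084). The list median was 1.29, with a camera adjusted p of 0.00613 and an adjusted p = 0.325 with an estimated correlation. Inflammatory activation genes had 5 of 12 higher in lung and 2 higher in heart, a median of 0.83 and a camera adjusted p of 0.0118 (adjusted p = 0.253 with an estimated correlation). Among them Icam1, a leukocyte adhesion gene, stood at 56.8 ± 8.79 CPM in heart and 307 ± 33.3 in lung (2.44, edgeR adjusted p = 2.0e-11).

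Antigen presentation genes of MHC class I and II were higher in lung in 4 of 10 cases, led by the invariant chain gene Cd74 at 27.3 ± 18.5 CPM in heart and 1249 ± 687 in lung (log2 5.52, edgeR adjusted p = 5.6e-07) and H2-Ab1 at 19.5 ± 11.5 and 503 ± 214 (4.69, adjusted p = 3.2e-07). The list median was 0.56 and the mean 2.19, with a camera adjusted p of 0.0653 (adjusted p = 0.753 with an estimated correlation). It passed with the cohort as a block in the 8 matrices of shared cohorts, where 2371 genes were called (camera adjusted p = 3.3e-05, against 0.0621 in these matrices without the block), without the filter (0.0171), in all called cells (0.0369), and without heart cohort 72 (0.00148), lung cohort 72 (0.0415) or lung cohort 70 (0.0479). Over these settings the adjusted p was 0.403 to 0.758 with an estimated correlation.

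Among VEGF genes, Vegfa was higher in the lung endothelial sums, at 84.5 ± 15.2 CPM against 3.25 ± 0.81 in heart (log2 4.74, SE 0.16, edgeR adjusted p = 4.2e-13). These lung sums also held epithelial RNA, with the surfactant gene Sftpc at 102 to 389 CPM per library. The Vegfa level therefore need not come from endothelial cells alone. The coreceptor gene Nrp2 was higher in heart, at 130 against 22.2 CPM (−2.56, edgeR adjusted p = 1.1e-08). Flt1 stood at 567.6 ± 203 CPM in heart and 348 ± 96.4 in lung (−0.71, adjusted p = 0.0225), short of the 2-fold minimum, and neither Kdr (−0.31, adjusted p = 0.266) nor Flt4 (0.53, adjusted p = 0.169) passed in edgeR. With the cohort as a block, in the 8 matrices of shared cohorts (2371 genes called), the adjusted p in edgeR was 0.00212 for Kdr and 0.00171 for Flt4, still under 2-fold. In the same 8 matrices without the block it was 0.316 for Kdr, 0.290 for Flt4 and 0.0901 for Flt1, and for Flt1 it was 0.0586 without cohort 120. These 3 averages include the libraries with low receptor counts. The list of VEGF receptors, coreceptors and ligands had 2 of 10 genes higher in lung and 1 higher in heart, a median of −0.05, a mean of 0.42 and a camera adjusted p of 0.654 with an upward sign. VEGF-responsive genes had 5 of 21 higher in lung and 4 higher in heart, a median of 0.26, a mean of −0.05 and a camera adjusted p of 0.647 with a downward sign.

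The remaining pathway lists did not pass in camera. Angiopoietin-Tie genes had a median of 0.56 (1 of 6 higher in lung, adjusted p = 0.168), junction genes 0.25 (2 of 9 higher in each tissue, adjusted p = 0.654) and p53 targets 0.45 (4 of 15 higher in lung, 1 in heart, adjusted p = 0.353). Notch genes had 3 of 12 higher in each tissue, with a median of 0.10, a mean of 0.04 and a camera test signed downward (adjusted p = 0.828). Flow-responsive genes had 2 of 8 higher in each tissue, with a median of −0.005 and a mean of −0.28 (adjusted p = 0.351). Apoptosis regulators had 1 of 18 higher in lung, with a median of −0.10, a mean of 0.25 and a test signed downward (adjusted p = 0.983). The cell cycle lists had medians of −1.08 for G2/M (0 of 12 genes called in edgeR and 1 at an unadjusted p under 0.05, camera adjusted p = 0.654) and −0.56 for G1/S (4 of 14 higher in heart, adjusted p = 0.266). Single genes within them differed, among them the tight junction gene Cldn5, at 944 ± 238 CPM in heart and 4731 ± 533 in lung (log2 2.33, edgeR adjusted p = 3.0e-09).

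Aerocyte markers, of the lung capillary cells that face the alveolus, were higher in lung in 7 of 8 cases, with a median of 2.44 and a camera adjusted p of 4.0e-11 (adjusted p = 0.00465 with an estimated correlation). They include Car4, at 744 ± 264 CPM in heart and 1743 ± 196 in lung (log2 1.23, edgeR adjusted p = 6.6e-05), and the endothelin receptor gene Ednrb (1.84, adjusted p = 1.3e-09). Lung general capillary markers had 4 of 9 higher in lung and 2 higher in heart, with a median of 0.95 (camera adjusted p = 1.4e-05; adjusted p = 0.0102 with an estimated correlation). Heart capillary markers, of which Fabp4, Cd36, Meox2, Tcf15 and Gpihbp1 also belong to the fatty acid uptake list and Car4 to the aerocyte list, had 8 of 9 higher in heart and 1 higher in lung, with a median of −5.63 (camera adjusted p = 6.2e-10; adjusted p = 0.0154 with an estimated correlation). With the cohort as a block (8 matrices, 2371 genes called) these 3 lists and the fatty acid uptake list passed with the preset correlation, but with an estimated correlation the adjusted p was 0.194 for aerocyte markers and 0.361 for each of the others. In the same 8 matrices without the block it was 0.0376 for each of the 4 lists. Venous markers were higher in lung in 6 of 10 cases and higher in heart in 0, with a median of 2.99 (camera adjusted p = 3.1e-06; adjusted p = 0.103 with an estimated correlation), among them Vwf, at 51.7 ± 14.7 CPM in heart and 375 ± 47 in lung. Arterial markers had 4 of 12 higher in each tissue and a median of −0.20 (camera adjusted p = 0.464). Pan-endothelial markers had a median of 0.37, with 2 of 8 higher in lung and 1 higher in heart (camera adjusted p = 0.414). Proliferating cell markers had a median of −1.24 and 0 of 8 genes called in edgeR, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.786).

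Lymphatic markers were higher in lung in 6 of 8 cases and higher in heart in 2, with a median of 3.15 and a camera adjusted p of 0.0328 (adjusted p = 0.325 with an estimated correlation). Lyve1, which encodes a hyaluronan receptor of lymphatic vessels, stood at 679 ± 124 CPM in lung and 5.86 ± 4.06 in heart. When clustered without genes 2-fold apart between libraries, Lyve1 was among the leading genes of the heart lymphatic-like cluster. It was not among those of the lung lymphatic-like cluster. The Lyve1 level in lung therefore need not measure lymphatic cells. The lymphatic list did not pass with the cohort as a block (0.554), in the 8 matrices of shared cohorts without the block (0.127), in all called cells (0.165), without heart cohort 72 (0.0517) or without lung cohort 64 (0.0808). Endocardial markers had 4 of 6 higher in lung and 1 higher in heart, with a median of 2.097 and a camera adjusted p of 0.0653 (adjusted p = 0.325 with an estimated correlation). That list passed with the block (0.0457), in the 8 matrices without it (0.0225), without the filter (0.0166), at a minimum of 500 UMIs (0.00159) or 2000 UMIs (0.00202), in all called cells (0.0472), without the highest doublet scores (0.0472), without heart cohort 82 (0.0431) and without lung cohort 70 (0.0484). There the adjusted p with an estimated correlation was 0.0336 at 500 UMIs, 0.0392 at 2000 UMIs and 0.186 to 0.497 in the others. Members of the endocardial list led other vessel classes in lung when clustered without genes 2-fold apart between libraries. Cytl1 led a venous-like (13.5-fold) and an arterial-like cluster (15.1-fold), and Hmcn1 a general capillary-like one (2.0-fold). In lung the list therefore need not measure endocardial cells.

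Transcripts of other cell types were present in the endothelial sums. Lung epithelial markers were higher in lung in 6 of 6 cases, with a median of 6.61 (camera adjusted p = 1.2e-04; adjusted p = 0.253 with an estimated correlation), and Sftpc, a surfactant gene of alveolar type 2 cells, stood at 173 ± 79.2 CPM in lung and 2.70 ± 2.97 in heart. Cardiomyocyte markers were higher in heart in 7 of 8 cases, with a median of −5.36 (camera adjusted p = 3.4e-07; adjusted p = 0.103 with an estimated correlation), and Tnnt2 stood at 19.9 ± 5.58 CPM in heart and 0.580 in lung. Erythrocyte markers had 5 of 5 higher in lung (median 2.95, camera adjusted p = 0.351). Immune markers had 3 of 6 higher in lung (5 adjusted over the list alone; median 1.17, camera adjusted p = 0.351). Platelet markers had 3 of 4 higher in lung (median 2.60, camera adjusted p = 0.266), and passed in all called cells (0.0106), without cohort 120 (0.0363) and without lung cohort 120 (0.0349). With an estimated correlation the adjusted p of platelet markers was 0.326, 0.330 and 0.278 in these settings. Fibroblast markers had 3 of 7 higher in each tissue, with a median of 0.61, a mean of −0.46 and a camera test signed upward (adjusted p = 0.881). Pericyte and smooth muscle markers had 2 of 8 higher in each tissue, with a median of 0.67, a mean of 0.15 and a test signed downward (adjusted p = 0.881). In all called cells camera passed the immune and fibroblast markers (adjusted p = 3.1e-05 for each) and the pericyte and smooth muscle markers (0.00299), and the adjusted p was 0.233, 0.225 and 0.301 with an estimated correlation. For every list but the immune markers, the counts adjusted over the list alone equal those over all genes.

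The number of genes at least 2-fold apart between the libraries of a matrix ran from 4 to 34 in heart and from 8 to 18 in lung. Heart R1R2 had 34 (14 higher and 20 lower in library 2), heart R1R2R3 34 (17 and 17), heart R1 29 (17 and 12), heart R2 14 (6 and 8), heart R2R3 8 (1 and 7) and heart R3 4 (2 and 2). Lung R1R2R3 had 18 (3 and 15), lung R1R2 13 (10 and 3), lung R1 12 (2 and 10), lung R2 11 (7 and 4), lung R3 9 (2 and 7) and lung R2R3 8 (1 and 7). The receptors are included. With 1 library per arm, mice, preparation and deletion cannot be told apart in these counts. They depend on the expression floor and on the cells used: at 20 CPM heart R1 had 76, heart R2 24, heart R3 8, heart R1R2 65, lung R1 21 and lung R3 22. In all called cells heart R3 had 9, heart R2R3 4, lung R3 51, lung R1R2 29, lung R2R3 24 and lung R1R2R3 31. At 2000 UMIs per cell heart R1R2 had 78 and lung R1R2 22, and at 500 UMIs lung R2 had 7 and lung R3 4.

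In heart R1, transcripts of dividing cells were higher in library 2: Top2a, a topoisomerase gene of dividing cells, stood at 9.83 CPM in library 1 and 52.7 in library 2 (36 and 301 counts). The stress gene Hspa1a went the other way, at 352 and 13.3 CPM (1290 and 76 counts), as did the vasoconstrictor gene Edn1 (53.2 and 7.36 CPM) and the linker histone gene Hist1h1c (168 and 61.8 CPM). Ift122, Tubb6 and the urokinase receptor gene Plaur were higher in library 2, at 47.8 and 203, 18.8 and 71.8, and 20.5 and 66.0 CPM. G2/M genes had a median log2 ratio of 1.52 and G1/S genes of 1.06, each above all 10000 random lists (percentile 100), with 5 of 5 and 11 of 11 members higher in library 2. In capillary cells alone the log2 ratio was 0.87 for Top2a (1.96 in all endothelial cells) and −1.21 for Edn1 (−2.24), and a single G2/M gene was measured, so no median could be given. VEGF-responsive genes had a median of 0.60 (percentile 100, 13 higher and 1 lower of 17), flow-responsive genes −0.53 (percentile 0) and immediate early and heat shock genes −0.36 (percentile 0, 2 higher and 8 lower). Arterial markers were lower in the same library (−0.33, percentile 0, 9 of 11), as were erythrocyte markers (−0.98, percentile 0).

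In heart R1R2 and heart R1R2R3, Igfbp3, an insulin-like growth factor binding protein gene of capillary cells, was lower in library 2 (434 against 95.4 CPM, and 365 against 120 CPM). Angptl4, the lipase inhibitor gene, was higher in library 2 of both (49.9 against 275 CPM, and 26.9 against 94.0 CPM). VEGF-responsive genes had medians of −0.29 in R1R2 (percentile 0.01, 6 of 15 lower, 1 higher and 8 with an interval including 0) and −0.42 in R1R2R3 (percentile 0, 10 lower and 5 higher). Notch genes had medians of −0.29 (percentile 0.05) and −0.43 (percentile 0). Markers of vessel classes moved in the same libraries, with arterial markers at −0.21 (percentile 1.09) and −0.25 (percentile 0.075, 7 of 11 lower) and venous markers at 0.61 (percentile 100) and 0.42 (percentile 99.99). In R1R2R3 endocardial markers stood at 0.74 (percentile 99.99, 2 of 3 higher and 0 lower) and erythrocyte markers at −0.37 (percentile 1.21). Interferon response genes had medians of 0.26 (8 of 15 higher, 1 lower and 6 with an interval including 0) and 0.51 (14 of 15 higher), at percentile 100 in each. In R1R2 the transcription factor genes Zbtb16 and Lhx6 and the histamine synthesis gene Hdc were higher in library 2 (32.3 and 118.0, 14.7 and 52.6, and 12.6 and 51.3 CPM), and Cytl1, an endocardial marker, was lower (65.4 and 3.09 CPM; log2 −3.12, and −0.50 in capillary cells alone). At 2000 UMIs per cell the log2 ratio of Lhx6 was 0.88, against 1.55. In R1R2R3 the endothelial transcription factor gene Sox18 (57.1 and 193 CPM) and the interferon-induced gene Irgm1 (39.8 and 133 CPM) were higher in library 2, and Ift122 (60.1 and 15.8 CPM) and Erdr1 (137.5 and 43.0 CPM) were lower. Fatty acid uptake genes in R1R2 had a median of 0.37 (percentile 99.97), inflammatory activation genes 0.50 (99.99) and immediate early genes 0.42 (percentile 100; 0.10 and percentile 91.9 at 2000 UMIs per cell). Dcn, a fibroblast transcript, stood at 84.3 and 2.65 CPM in R1R2 (log2 −3.54, and 0.20 in capillary cells alone).

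In heart R2, antigen presentation genes were lower in library 2, with Cd74 at 99.2 and 16.8 CPM and H2-Ab1 at 60.4 and 16.4 CPM. In capillary cells alone the log2 ratio of Cd74 was −0.50, against −2.26 in all endothelial cells. The list median was −0.64 (percentile 0, 9 of 9 members lower). In lung R2, from the same cohort, Cd74 stood at 3943 and 1688 CPM, H2-DMa at 192 and 87.6 CPM, and the list at −0.59 (percentile 0, 10 of 10 lower). The lung R2 libraries also differed in erythrocyte markers (3.89, percentile 100, 4 of 4 higher), lymphatic markers (−0.64, percentile 0) and lung epithelial markers (0.50, percentile 99.99). The interferon-induced GTPase gene Igtp (169.6 and 76.25 CPM) and the transcription factor gene Maf (65.7 and 27.0 CPM; log2 −1.14, and −0.15 in capillary cells alone) were lower in library 2 of lung R2. Tpm3-rs7, a gene related in sequence to Tpm3 that can share its reads, was higher in library 2 in both tissues (18.2 and 196.5 CPM in heart, 10.7 and 93.2 CPM in lung). The circadian gene Dbp (174 and 418 CPM), Ier3 (84.7 and 202 CPM) and Cyr61 (74.4 and 177 CPM) were higher in library 2 of heart R2, and Igfbp3 was lower (378 and 148 CPM). Notch genes in heart R2 had a median of −0.22 (percentile 0.02).

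Heart R3 and heart R2R3 had few genes 2-fold apart. In heart R3 the immediate early gene Fos was higher in library 2 (63.5 and 145.0 CPM), and the caveolin gene Cav2 (747.5 and 363 CPM) and Serinc3 (489.9 and 234.9 CPM) were lower. The immediate early list had a median of 0.51, p53 targets 0.27, interferon genes 0.24 and hypoxia genes 0.23, each at percentile 100. In heart R2R3 the xenobiotic metabolism gene Cyp1a1 (50.2 and 10.9 CPM), the neurotensin gene Nts (72.1 and 29.0 CPM) and Dcn (55.7 and 20.5 CPM; log2 0.06 in capillary cells alone) were lower in library 2. Interferon genes had a median of 0.30 (percentile 100, 13 of 15 higher), p53 targets 0.29 (99.99) and Notch genes −0.15 (0.06). A copy of the lymphatic chemokine gene Ccl21a was higher in library 2 of heart R3 (105 and 288 CPM), R2R3 (101 and 386 CPM) and R1R2R3 (5.64 and 298 CPM) and lower in R2 (185 and 0.212 CPM, 1009 and 1 counts). In capillary cells alone its log2 ratio was 0.06 in R1R2R3 (4.83 in all endothelial cells), −0.85 in R2 (−5.19), 0.47 in R3 (1.41) and 1.16 in R2R3 (1.89). Near-identical copies of this gene share reads and differ in number between strains, so its level is uncertain.

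In lung R1, Cyp1a1 stood at 9.69 CPM in library 1 and 209 in library 2, and Zbtb16 at 57.1 and 131 CPM. Fabp4 (1183 and 129 CPM), Timp4 (54.5 and 13.8 CPM) and Fabp5 (65.1 and 18.3 CPM) were lower in library 2, and the fatty acid list had a median of −0.82 (percentile 0). That median was 0.08 in capillary cells alone, where the log2 ratio was −1.30 for Fabp4 (−3.14 in all endothelial cells), −0.32 for Timp4 (−1.66) and −0.44 for Fabp5 (−1.59). Lung cluster 19 held 43.1 to 94.4% of the Fabp4 UMIs of a lung library. In lung R3 Fabp4 was also lower in library 2 (885 and 239 CPM; log2 −1.87, and −1.64 in capillary cells alone), while in lung R2 it was higher (113 and 263 CPM; log2 1.18, and −0.06 in capillary cells alone). In lung R3 Creb5 (35.0 and 75.5 CPM) and Sox18 (106 and 217 CPM) were higher in library 2 and Ttc39c was lower (68.4 and 29.3 CPM). Notch genes there had a median of 0.38 and VEGF-responsive genes of 0.27 (percentile 100 in each), and antigen presentation genes of −0.29 (percentile 0, 8 of 10 lower). Arterial markers moved in the same libraries, with a median of 0.23 (percentile 99.89, 4 of 9 higher and 1 lower), as did endocardial markers, at 0.42 (percentile 99.61, 2 of 3 higher and 1 lower).

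In lung R1R2R3, aerocyte markers were higher in library 2, with a median of 0.55 (percentile 100, 8 of 8 members), and venous markers were lower, at −0.46 (percentile 0, 7 of 8). The checkpoint kinase gene Chek2 (77.0 and 11.2 CPM) was lower in library 2, and Ccdc184 (32.0 and 90.7 CPM) was higher. The p53 targets had a median of 0.37 (percentile 100, 8 higher and 0 lower of 11). In lung R1R2 Chek2 (56.2 and 16.0 CPM) and Antxr2 (53.2 and 22.75 CPM) were lower, and Erdr1 (16.9 and 55.7 CPM), Serpina3g (19.9 and 52.3 CPM) and Ccdc184 (41.3 and 100.2 CPM) were higher. Notch genes had a median of −0.31 and antigen presentation genes of −0.38 (percentile 0 in each). In lung R2R3 Lpl was higher in library 2 (228.5 and 496 CPM), and Cyp1a1 (515 and 222.5 CPM), Nr4a1 (62.6 and 26.2 CPM) and Tmem252 (242 and 113 CPM) were lower. Immediate early genes there had a median of −0.43 (percentile 0, 13 of 14 lower) and interferon genes of 0.23 (percentile 100). The club cell transcript Scgb1a1, which is not endothelial, stood at 26.9 and 534.5 CPM in lung R2, 128 and 59.3 in R3, 248 and 729 in R1R2, 388 and 99.3 in R2R3, and 42.6 and 192 in R1R2R3.

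Markers of other cells and vessel classes differed between the libraries of further matrices. Erythrocyte markers had medians of −0.78 in heart R3, −0.57 in heart R2R3, −2.06 in lung R1, −1.40 in lung R3 and −0.73 in lung R1R2 (percentile 0 in each) and of 0.59 in lung R1R2R3 (percentile 100). Lung epithelial markers had medians of −1.13 in lung R2R3 (percentile 0) and −0.68 in lung R1R2 (percentile 0.025). Aerocyte markers had medians of 0.23 in lung R1R2, −0.26 in lung R2R3, −0.25 in lung R3 and −0.15 in lung R1. Heart capillary markers had medians of −0.77 in lung R1 (percentile 0) and −0.29 in lung R3 (percentile 0.415). Lymphatic markers had medians of 0.49 in lung R1 (percentile 99.98) and 0.32 in lung R1R2R3 (percentile 99.88), and endocardial markers of −0.35 in lung R1R2R3 (percentile 0.465).

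Of 181 medians of pathway lists in the 12 matrices, 83 lay outside the central 95% of random lists. Whether a list differed more between the libraries of cohorts whose label names a given receptor was tested 45 times by exact permutation (two-sided). In this test 0 passed, 0 had an unadjusted p under 0.05, and the lowest adjusted p was 0.643. The smallest exact permutation p that the splits can give is 0.0179 for R2 and R3 and 0.0286 for R1. A single list at that p would not pass over 45 tests. Lists without a median in every matrix were not tested. The lowest exact permutation p, 0.0536, belonged to VEGF receptors, coreceptors and ligands with R2 (5 cohorts against 3, a difference of 0.32), a list that holds the deleted genes, and to fatty acid uptake with R3 (−0.16). No other tool was run on this question.

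Arterial-like cells, named from arterial markers, were a smaller share of heart endothelial cells in library 2 of R1R2R3 (14.5% with a 95% interval of 13.05 to 16.0, against 7.70%, 6.64 to 8.87) and of R1R2 (14.9%, 13.1 to 16.8, against 9.44%, 7.98 to 11.1). The shares were 13.2 and 10.3% in R1, 13.8 and 11.1% in R2, 9.85 and 10.7% in R3, and 10.4 and 8.99% in R2R3. When the cells were clustered without genes 2-fold apart between libraries, the shares were 19.3 and 14.8% in R1R2R3, 19.8 and 16.6% in R1R2, 19.5 and 13.7% in R1 and 17.8 and 17.8% in R2, over a smaller endothelial total, since a pair of clusters (1176 and 159 cells) then fell outside it. Proliferating-like cells were 10 of 1880 (0.532%, 0.255 to 0.976) in library 1 of heart R1 and 79 of 2417 (3.27%, 2.60 to 4.06) in library 2, and at most 0.155% in the other heart libraries. Their cluster of 104 cells took 85.6% of its cells from heart R1. Venous-like cells made 4.65 to 10.5% of the endothelial cells of a heart library (2.38 to 5.47% when clustered without those genes) and lymphatic-like cells 0 to 0.443%.

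Aerocyte-like cells were a larger share of lung endothelial cells in library 2 of R1R2R3, at 21.6% (19.6 to 23.7) in library 1 and 35.0% (32.3 to 37.7) in library 2, and general capillary-like cells a smaller one, at 55.4 and 43.3%. The aerocyte-like shares were 20.9 and 27.5% in R1R2, 29.8 and 25.4% in R1, 19.5 and 20.8% in R2, 24.5 and 25.9% in R3, and 25.4 and 22.9% in R2R3. Arterial-like cells made 9.57 to 16.8% of the endothelial cells of a lung library (15.4 to 22.3% when clustered without genes 2-fold apart), venous-like cells 4.77 to 10.1% and lymphatic-like cells 1.42 to 2.78%. The size of the difference in share between libraries was compared between the 4 matrices that name R2 and the other 2 of each tissue. For heart arterial-like cells it was 2.22 points larger with R2 (exact permutation, two-sided, p = 0.333), for heart venous-like cells 1.56 (exact p = 0.4), for lymphatic-like 0.12 (exact p = 0.267) and for proliferating-like −1.34 (exact p = 0.267). In lung it was 3.08 for aerocyte-like cells (exact p = 0.667), −1.24 for arterial-like (exact p = 0.4), 2.52 for general capillary-like (exact p = 0.4), 0.83 for venous-like (exact p = 0.533), −0.04 for lymphatic-like (exact p = 0.933) and −1.59 for a heart capillary-like cluster (exact p = 0.0667). The 15 splits give no p below 0.0667, so this design cannot reach 0.05.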

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

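The test of Sftpc on epithelial barcodes of all 3 lung matrices and the test for free RNA were chosen after the values had been seen, in place of a bound, written beforehand, whose control matrices turned out to be sources themselves.

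Among 60 groups of at least 4 matrices, 7 held a matrix set apart from its group, where chance gives about 1 in 20. In heart, Sema3c in R1R2 stood at 0.861 CPM (others 0 to 0.289), a value near the floor, since all 6 heart matrices together held 11 Sema3c counts. Aqp7 in heart R1R2 stood at 928 CPM (555 to 689), Rbp7 in heart R1 at 1544 (683 to 976) and Tcf15 in heart R2R3 at 1338 (837 to 995). In lung R1, Gm12002 stood at 9.51 CPM (others 0.527 to 2.36) and Tcf15 at 29.3 (7.26 to 14.3). The unsigned log2 ratio of Flt4 between libraries was 0.74 in heart R1, on 84 and 238 counts, and 0.08 to 0.30 in the other matrices that do not name R3.

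Barcodes of at most 100 UMIs, which hold no cell and are outside the comparisons of cells, carried the alveolar type 2 transcript Sftpc in heart libraries. It stood at 2925 and 2681 CPM in the libraries of heart R1, 1943 and 1718 in heart R2, and 3081 and 2815 in heart R1R2. In heart R3 it was 0 and 0, and in heart R1R2R3 0.462 and 0. If part of these molecules belongs to other libraries, which the tests on barcodes bear on, these values do not measure free RNA alone.

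Free lung RNA in the heart suspension met its bound written beforehand, since no cohort showed a clear excess on its own lung cells. The test chosen later argues against it as the whole source. Of these UMIs, 18.85 to 22.65% lay on epithelial barcodes of the lung matrices of cohorts 69, 70 and 72. That was at least 341 times what an even spread over barcodes gives. UMIs that lay on no called lung cell may still include free RNA, which was not tested. Molecules of the same cohort's lung library read under heart indices, tested as planned, are argued against as the whole source: same-cohort lung cells held 0.407 (heart R1), 0.718 (heart R1R2) and 1.11 (heart R2) times the share on cells of the highest other lung matrix, where this source needs a clear excess in each. The values are consistent with molecules of the lung libraries of cohorts 69, 70 and 72 together being read under heart library indices, since UMIs per epithelial barcode of these 3 lung matrices were at least 44.7 times those of the other 3. On called cells of the 3 lung matrices lay 21.0 to 24.4% of the UMIs, against 1.61 to 1.84% on the other 3. No biological explanation was tested.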

How the results depend on the processing

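The fits without high doublet scores, without shared barcodes, without lung cluster 19, without cohort 120, and in the 8 matrices of shared cohorts without the block, and the clustering without genes 2-fold apart between libraries, were chosen after the data had been seen. The 8 alternatives to the deletion effect were not run, because no source ties a library to the control or the deletion arm. Of the values that answer a comparison, 199 counted as the same, 18 moved, 8 reversed and 22 no longer passed, against 27 values reported. To count as the same, gene and list counts had to stay within a fixed fold, and receptor tests had to keep sign and side of the threshold. Shares had to keep sign alone, so heart venous-like cells at 1.56 and 0.046 points counted as the same. Of single genes and lists, 1973 counted as the same, 101 moved and 11 reversed, against 214 reported. Heart against lung genes had to keep sign and side of the threshold, whatever their size. Ratios between libraries had to stay within a range. The cause was not tested unless stated. Libraries of 2010521 to 11819992 endothelial UMIs limit genes near the floor.

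The count of genes called between heart and lung was 3827 without the filter on low counts and 5924 without the fold minimum, which follow from testing or admitting more genes. With the cohort as a block, in 8 matrices, it was 2371, of which 2213 were shared with the 2327 called in all 12; it was 2306 in the 8 without the block. Among lists the block changed the camera call for MHC genes, while the lymphatic call was lost and the endocardial call gained in the 8 matrices with or without it. With an estimated correlation the block lost the calls of aerocyte markers (adjusted p = 0.194), general capillary markers, heart capillary markers and fatty acid uptake (0.361 each), against 0.0376 each in the 8 without it. The difference in unsigned receptor ratios no longer passed in heart alone (Flt1 1.31, Kdr 1.16, Flt4 1.91) or lung alone (2.62, 0.74 and 2.69), since fewer splits raise the smallest p. Leaving out each cohort gave 1.66 to 2.25 for Flt1, 0.79 to 1.11 for Kdr and 2.19 to 2.42 for Flt4 with calls kept for all 3 without cohort 59 or 69 and for Flt1 and Flt4 without cohort 82, and lost otherwise.

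Genes 2-fold apart between libraries numbered, at 20 CPM, 76 in heart R1, 24 in heart R2, 8 in heart R3, 65 in heart R1R2, 21 in lung R1 and 22 in lung R3, as more genes enter. In all called cells they numbered 9 in heart R3, 4 in heart R2R3, 51 in lung R3, 29 in lung R1R2, 24 in lung R2R3 and 31 in lung R1R2R3. At 2000 UMIs they numbered 78 in heart R1R2 and 22 in lung R1R2, and at 500 UMIs 7 in lung R2 and 4 in lung R3.

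Differences in share with R2 reversed, though none passed in any setting: at 2000 UMIs heart arterial −1.93, heart venous −1.73 and lung arterial 1.84 points; by marker score lung arterial 0.18 and lung lymphatic 0.19; at 500 UMIs lung lymphatic 0.032; clustered without genes 2-fold apart, heart arterial −1.03 and lung arterial 1.123.

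Among named genes and receptors whose interval excludes 0, and lists outside the central 95% of random lists, log2 ratios between libraries reversed in capillary cells alone for immediate early genes in heart R1R2R3 (−0.019), VEGF receptors in lung R1 (−0.032) and lung R2R3 (0.028), fatty acid uptake in lung R1 (0.079), Dcn in heart R1R2 (0.20) and heart R2R3 (0.057), Fabp4 in lung R2 (−0.062) and Flt4 in lung R2 (0.0040). They also reversed at 50 CPM for VEGF receptors in lung R1 (−0.0021), and at 2000 UMIs for VEGF-responsive genes in heart R3 (−0.038) and Dcn in heart R2R3 (0.095).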

Other observations

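The margin used for genes shared by both tissues, the count that includes the receptors and the test of other splits of the heart and lung matrices were chosen after the results had been seen. Igfbp3, an insulin-like growth factor binding protein gene, differed between libraries in both directions across heart matrices. It stood at 290 CPM in library 1 and 453 in library 2 of R1, 378 and 148 in R2, 302 and 317 in R3, 434 and 95.4 in R1R2, 337 and 214 in R2R3, and 365 and 120 in R1R2R3. Esm1, a tip cell gene that VEGF induces, stood at 30.3 and 65.9 CPM in heart R1 and at 30.4 and 11.3 in R1R2R3. The carbonic anhydrase gene Car4 stood at 501 and 1159 CPM in heart R1R2 and at 485 and 1005 in R1R2R3, and the VEGF coreceptor gene Nrp1 at 956 and 534 and at 975.4 and 532. No test was made on these values, which come from 1 library each and were picked after being seen.

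In cohort 72 (R2), Cdkn1a, a p53 target, was lower in library 2 of both tissues, at 1185 and 622 CPM in heart and 1165 and 625.2 in lung. The p53 target list, which includes Cdkn1a, did not follow it as a whole. The list had a median log2 ratio of 0.14 in heart R2 (3 members higher and 2 lower) and 0.073 in lung R2 (3 and 2). In lung R1R2R3 Cdkn1a was higher in library 2, at 587 and 1011 CPM, with 8 of 11 list members higher.

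The 2327 genes called between heart and lung were matched by 1 of 100 splits of the 12 matrices, the real one, and the highest other split called 1 gene. Every other split mixed heart and lung matrices in both groups, so the tissue difference became spread within groups. Such splits could hardly call genes. The test therefore cannot decide how many of the 2327 calls are false.

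Lung cluster 19 held 345 cells, 0.665 to 4.25% of the endothelial cells of a lung library, with heart capillary transcripts. Its heart-higher named genes summed to 13050 CPM, 39.3% of the heart level, against 69.6 in other lung endothelial cells. Heart cells of the same cohort read under lung library indices are argued against as its source, since 0% of 243 cells in cohorts with both tissues shared a barcode with a called heart cell of their cohort. Heart cells of other cohorts were not compared. Heart cells carried into the lung suspension may be a source: lung-higher genes stood at 17.8% of other lung endothelial cells (1248 against 6992 CPM, and 4.47 in heart), a level that free lung RNA or mixed droplets could also give, so this cannot be told apart from lung cells with such a profile. The latter was not tested.

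Genes 2-fold apart between libraries in both tissues of a cohort, leaving out the 3 receptors that the labels name, numbered 8: Hba-a1 in cohort 69, Zbtb16 in 70, Cd74, Hbb-bs, Igtp and Tpm3-rs7 in 72, and Cyp1a1 and Gm10036 in 120. Over 24 pairings of heart and lung matrices the highest other count was 7 (exact permutation, one-sided, p = 0.0417, the smallest possible). With the receptors, which added Flt1 in 69 and 70 and Kdr in 120, it was 11 against 10 (exact permutation p = 0.0417). Either count passed the bound written beforehand, above every other pairing. A margin of 1 gene does not separate differences particular to a cohort from genes that vary between any pair of libraries. Reads moved between Tpm3-rs7 and Tpm3 may account for part of the former: the difference of their sum was 39% of the Tpm3-rs7 difference in lung and 50.9% in heart, which leaves this open. Differences between mice, which both tissues of a cohort may share, were not tested.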
